A study of Mus musculus with 2 samples.

How the data were processed

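CTCF binding was mapped by chromatin immunoprecipitation followed by sequencing in mouse embryonic stem (ES) cells and in mouse embryonic fibroblasts (MEFs), with 1 library per cell type. Per the labels' protocols, sonicated nuclei were cleared, DNA was recovered with an antibody against CTCF, and Illumina libraries were sequenced on a Genome Analyzer. The submitters' processing notes name the genome build mm9. The aligner, the peak caller, its threshold, any input control and any filter are not given in the sources used here, and neither is the number of reads, so the depth of each library is unknown. An input or control-antibody background was not analysed here.

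The deposited file of each library is a list of peaks with a chromosome, a start, an end and a whole-number score for each peak. The authors deposited 1 list per library, and the labels do not say whether several preparations were pooled in it. The deposited score is not defined in the labels or in the files, which have no header. It was therefore used only to rank peaks within its own list. Score values were not compared between lists, but ranks were, in a rank correlation over shared peaks and in the overlap of the highest-ranked peaks of both lists. Every peak spans 399 bp when the file is read as BED, or 400 bp if both ends are counted, so the width of a peak carries no information. Starts of neighbouring peaks in a list lie at least 201 bp apart, and 984 neighbouring pairs in the ES list and 1253 in the MEF list overlap each other. Positions are printed counting from 1, with 1 added to the deposited start. If the deposited starts already counted from 1, each printed start lies 1 base too far to the right.

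A peak was called shared when it overlapped a peak of the other list by at least 1 bp. Because all peaks have 1 width, this was computed from the distance between starts, and the counts were checked with bedtools 2.31.1. The method was tested on simulated lists with as many peaks per chromosome as the real ones. Simulated peaks were placed uniformly, and planted partners lay within 100 bp, so that each planted partner overlapped by construction. The test therefore checks the counting and the chance correction, and not lists with clustered peaks or larger offsets. With 25% of 44424 simulated ES peaks planted at matching positions, 26.3% overlapped, and 1.67% overlapped after the other list was moved by 10 kb. Correcting for this chance overlap, as the difference divided by the share of peaks not overlapping by chance, gave 25.1%. The excess values reported for the real lists are plain differences without this division. Chance overlap was measured in 100 placements in which the other list was rotated by a random distance within each chromosome. Percentages carry 95% Wilson intervals, and ratios of peak numbers carry 95% exact binomial (Clopper-Pearson) intervals. These intervals cover counting error only. They treat peaks as independent and say nothing about the spread between cultures, which 1 library per cell type cannot give. For the same reason no p-value was computed. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

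Per-chromosome comparisons used the 19 autosomes and X. Windows of 1 Mb were counted from the first base of each chromosome, and a peak belonged to the window that held its midpoint. Windows without a peak in either list were left out of all counts of windows. Chromosome spans were taken as the end of the last peak in either list. The definitions, the lists of alternatives and the rule for naming regions were fixed before the data were examined. The rule took the 5 highest-scoring shared and the 5 highest-scoring cell-type-only peaks of each list, the 3 windows with most peaks, and the 3 windows with the largest difference in the percentage of peaks not shared among windows with at least 20 peaks in the union. Alternatives were a reciprocal overlap of 50%, midpoints within 500 bp, the higher-scoring 50% of a list, the MEF list cut by score to the length of the ES list, merged peaks, uniform placement for the chance overlap, and windows of 500 kb. Genomic annotation, motif content and gene lists had also been planned. They needed a genome or an annotation of the mm9 build, and the only gene table at hand follows another build (GRCm38.p6) and was not used, so these were not analysed here and no gene names are attached to positions.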

Results

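CTCF is a zinc-finger DNA-binding protein found at insulators and at the borders of chromatin loops. Its binding sites were mapped across the mouse genome in 2 cell types, ES cells, which are pluripotent cells derived from the early embryo, and MEFs, which are connective-tissue cells grown from later embryos. The question was where CTCF is bound in each cell type. The ES library gave 44424 peaks and the MEF library 53736, so that the MEF list was 1.21 times as long (95% interval 1.19 to 1.22). The same catalogue antibody was used for both libraries. The labels give different genetic backgrounds, Bl3.10 and C57BL for the ES cells and C57BL6 for the MEFs, so cell type, background and library cannot be told apart. There were no replicates, and every interval below covers counting error only.

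Peaks were spread over all 19 autosomes and X in both cell types. On autosomes the density was 17.6 peaks per Mb in ES cells and 21.1 peaks per Mb in MEFs. The median distance between the starts of neighbouring peaks was 22.4 kb in ES cells (quartiles 6.91 and 60.3 kb) and 22.3 kb in MEFs (quartiles 7.03 and 56.3 kb). Close pairs made up a small part of each list. In ES cells 11.9% of peaks had another ES peak within 1 kb, and in MEFs 11.3% had another MEF peak within that distance.

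Most peaks were called in 1 cell type only, and the shared part was larger in the ES list than in the MEF list. Of the ES peaks, 11595 (26.1%, 95% interval 25.7 to 26.5) overlapped a MEF peak, and 11617 MEF peaks (21.6%, 95% interval 21.3 to 22.0) overlapped an ES peak. The remaining 32829 ES peaks and 42119 MEF peaks had no overlapping partner. This means only that no peak was called there in the other list. Reads at these positions were not examined, and depth and threshold are unknown. Binding too weak to be called in the other cell type is therefore not excluded. The number of shared peaks was nearly equal in both lists, so the lower MEF percentage came with the longer MEF list. Chance overlap was far lower. Rotating the other list within each chromosome gave a mean of 1.69% for ES peaks (range of 100 placements 1.47 to 1.90) and 1.40% for MEF peaks (range 1.26 to 1.56). The observed overlap was 15.4 times this chance level in either list. Against the overlap left after the other list was moved by 10 kb, which keeps the regional density of peaks, it was 8.21 times for ES peaks and 8.22 times for MEF peaks.

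Shared peaks lay at almost the same bases. The median distance between an overlapping ES peak and its nearest MEF peak was 45 bp (quartiles 20 and 107 bp), and 73.4% of these ES peaks lay within 100 bp of their partner. When the MEF list was moved by 0.25 kb, less than the width of a peak, 25.4% of ES peaks still overlapped. After a move of 0.5 kb, more than the width of a peak, the overlap of ES peaks dropped to 8.04%. After a move of 10 kb it was 3.18%. The corresponding values for MEF peaks were 21.1%, 6.73% and 2.63%. The overlap after a 10 kb move was higher than after rotation along the chromosome.

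**Figure D1:**
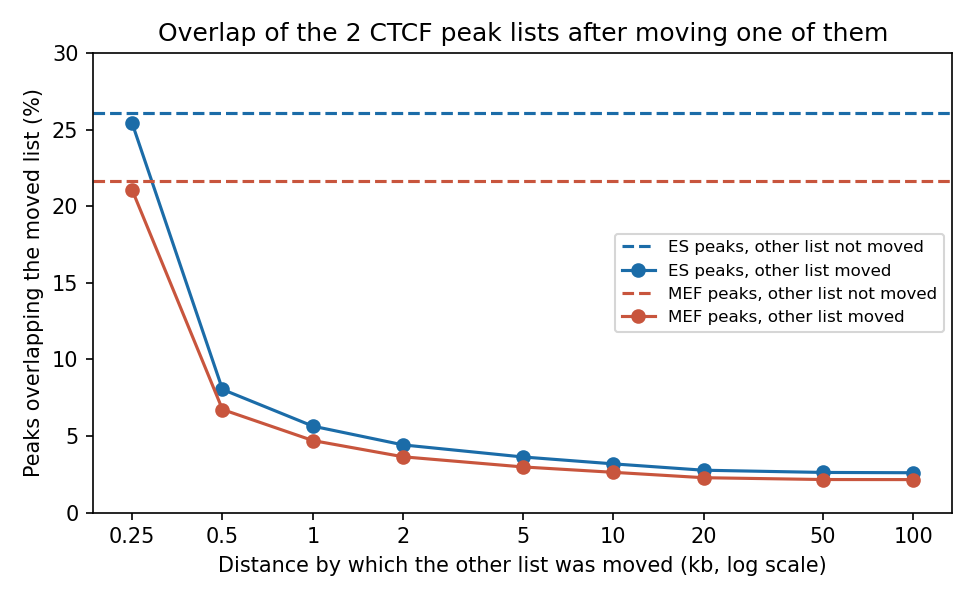
Percentage of ES and of MEF peaks (y axis) that overlap the other list after the other list was moved by the distance on the x axis (kb, log scale; each point is the mean of a move in either direction, dashed lines the unmoved lists). Overlap drops from 26.1% and 21.6% without a move to 8.04% and 6.73% at 0.5 kb and is 3.18% and 2.63% at 10 kb.

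Peaks with the highest scores were shared most often in both cell types. Each list was divided by score into 10 groups of equal size. In the highest-scoring group of the ES list, 49.9% of 4443 peaks overlapped a MEF peak (95% interval 48.4 to 51.3), and in that of the MEF list 55.2% of 5374 peaks overlapped an ES peak (53.8 to 56.5). Among the 1000 highest-scoring peaks the shared percentage was 68.0% in ES cells (65.0 to 70.8) and 74.2% in MEFs (71.4 to 76.8). Among the 100 highest it was 94.0% and 99.0%. A high score need not mean strong CTCF binding, because the score is not defined and no input background was analysed. Mitochondrial peaks also ranked high, with median scores of 345 (ES) and 200 (MEF), and 13 of 15 and 20 of 21 of them were shared. Below the highest 3 groups the percentage was nearly level. It lay between 20.1% and 24.2% in ES cells and between 14.2% and 16.9% in MEFs. The lowest-scoring group of the ES list was shared more often (24.2%, 23.0 to 25.5) than the group ranked 8 from the top (20.1%, 18.9 to 21.3).

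Shared peaks had a higher median score than the rest of their list. In ES cells the median score was 80 for shared peaks (quartiles 51 and 123) and 67 for ES-only peaks (46 and 94). In MEFs it was 64 for shared peaks (42 and 100) and 46 for MEF-only peaks (34 and 62). Ranks within the lists went together only weakly. Across the 11595 shared ES peaks, taken with their nearest MEF peak, Spearman's rho between the score ranks in the lists was 0.18; peaks are not independent replicates. Of the highest-scoring 10% of ES peaks, 20.04% overlapped a peak in the highest-scoring 10% of the MEF list (95% interval 18.9 to 21.2).

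**Figure D2:**
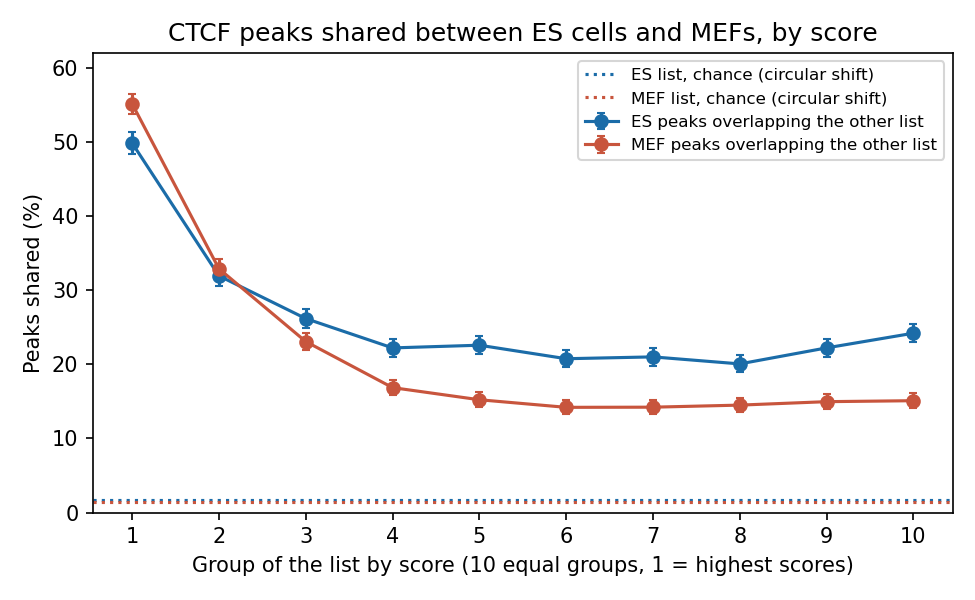
Percentage of peaks shared with the other cell type (y axis) for 10 groups of equal size of the ES and of the MEF list ordered by score (x axis, 1 is the highest), with 95% Wilson intervals as bars and the mean chance overlap as dotted lines. The highest group reaches 49.9% in ES cells and 55.2% in MEFs, and groups 4 to 10 stay between 14.2% and 24.2%, above chance at 1.69% and 1.40%.

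The highest scores belonged to a handful of positions that were nearly identical in both cell types. The top peak of either list was on chromosome 2, at 90256534 to 90256932 in ES cells with a score of 313002 and at 90256538 to 90256936 in MEFs with a score of 323957. Next in both lists came a peak on chromosome 9 at 101020502 to 101020900, which had the same coordinates in ES cells and MEFs. Peaks on chromosome 3 at 55976244 to 55976642 and on chromosome 1 at 170709615 to 170710013 also had identical coordinates in both lists. The fifth was on chromosome 17 at 39982654 to 39983052 in ES cells and on chromosome 2 at 98506723 to 98507121 in MEFs. Of the 10 highest-scoring peaks of each list, 9 overlapped one of the 10 highest of the other. The list medians were 70 in ES cells and 48 in MEFs. The score is not defined and no input background was analysed. These positions therefore need not be the strongest CTCF sites, and background signal common to both libraries cannot be told apart from binding.

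The peaks called in 1 cell type only had far lower top scores, and several of them lay just beside a peak of the other list. The highest ES-only peak was on chromosome 5 at 143665934 to 143666332 with a score of 5630, and a MEF peak started 531 bp away. ES-only peaks followed on an unplaced sequence (5495702 to 5496100, score 908), on chromosome 6 (127075623 to 127076021, score 861), on chromosome 8 (19982690 to 19983088, score 705) and on the mitochondrial genome (5263 to 5661, score 582). The nearest MEF peak was at most 2.03 kb away from any of these 5. The highest MEF-only peak was on the same unplaced sequence as the ES-only peak above (5496130 to 5496528, score 1103). It lay 428 bp from that ES-only peak and 403 bp from another ES peak, so these were neighbouring calls in both lists at 1 place. The others were on chromosome 5 at 125349355 to 125349753 with a score of 353, on chromosome 2 at 28225250 to 28225648 with a score of 344, on chromosome 4 at 33105318 to 33105716 with the same score, and on chromosome 19 at 5727749 to 5728147 with a score of 311. The chromosome 5 peak was the most isolated, 16.5 kb from the nearest ES peak, and the chromosome 2 peak lay 5.13 kb from one.

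The X chromosome differed from the autosomes in both cell types. It carried 802 ES peaks and 1393 MEF peaks, or 4.82 and 8.37 per Mb, below the density of any autosome. The ratio of MEF to ES peaks was 1.74 on X (95% interval 1.59 to 1.90) and 1.20 over all autosomes (1.18 to 1.22). Among the 19 autosomes the ratio was 1.22 ± 0.095 (SD over chromosomes), from 1.02 on chromosome 5 to 1.38 on chromosome 3, so X lay outside their range. Fewer X peaks were shared, but the shared percentage was not compared at matched peak density, so the part that density plays was not tested. On X 17.8% of ES peaks (15.3 to 20.6) and 10.4% of MEF peaks (8.91 to 12.1) had a partner, whereas on single autosomes the values ran from 22.2% to 30.6% for ES peaks and from 17.7% to 26.5% for MEF peaks. Chromosome 11 had the highest density in both cell types, 28.0 ES and 30.7 MEF peaks per Mb, and a ratio of 1.10. Chromosome 19 had the highest shared percentage of ES peaks (30.6%) and chromosome 11 that of MEF peaks (26.5%).

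**Figure D3:**
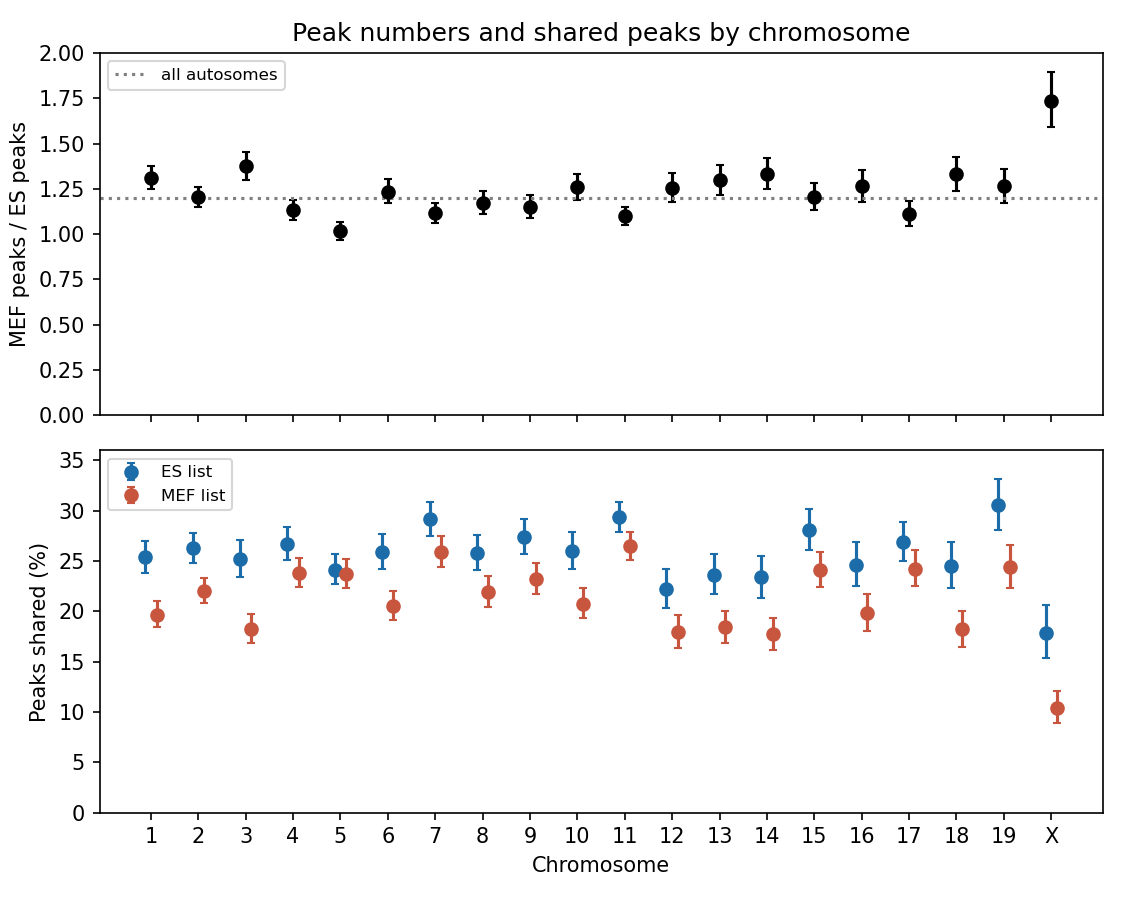
Upper panel, the ratio of MEF to ES peaks on each chromosome with 95% exact binomial intervals and the ratio of all autosomes (1.20) as a dotted line; lower panel, the percentage of ES and of MEF peaks shared on each chromosome with 95% Wilson intervals. X has the highest ratio (1.74) and the lowest shared percentages (17.8% and 10.4%).

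The surplus of MEF peaks was largest in windows that were poor in shared peaks. In the 529 autosomal 1 Mb windows without a shared ES peak, there were 1.70 MEF peaks per ES peak (95% interval 1.62 to 1.79). The ratio was 1.42 (1.36 to 1.49) in the 251 windows with 2 shared peaks and 1.22 (1.18 to 1.27) in the 273 windows with 5 to 6. In the 56 windows with 21 to 47 shared peaks, MEF and ES peaks were about equally frequent, at a ratio of 1.03 (0.979 to 1.08). Shared peaks enter both sides of this ratio and pull it towards 1. The ratio of MEF-only to ES-only peaks was 1.70, 1.51, 1.30 and 1.06 in the same groups, in order. Grouped by the peaks of both lists together, the autosomal ratio was 1.71 (1.59 to 1.83) in windows with 10 to 14 peaks and 1.03 (1.01 to 1.05) in windows with 60 or more. It did not keep rising in sparser windows. In the 158 windows with 5 to 9 peaks it was 1.53 (1.36 to 1.73). In the 32 windows with fewer than 5 peaks it was 1.11, with an interval (0.690 to 1.79) that includes each of these values. The 10% of windows with most shared peaks (240 windows) held 22.9% of all autosomal ES-only peaks (22.4 to 23.3) and 18.8% of MEF-only peaks (18.5 to 19.2). Peak numbers per window still went together in the 2 cell types, with a Spearman's rho of 0.88 across the 2406 windows that held a peak, which are not replicates. The MEF share of peaks varied between windows 1.32 times as much as binomial counting error alone gives (variance ratio).

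**Figure D4:**
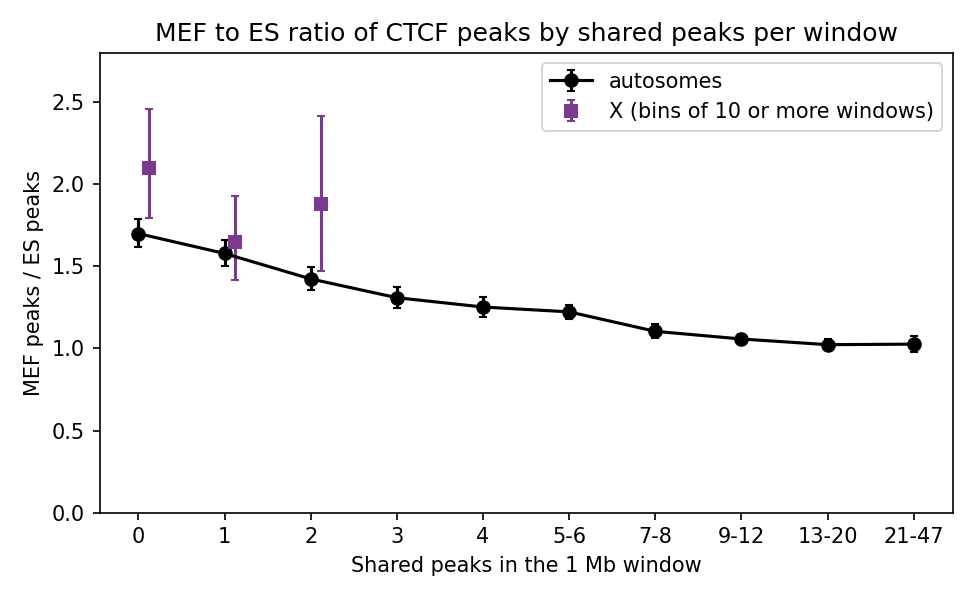
Ratio of MEF to ES peaks (y axis) in 1 Mb windows grouped by their number of shared ES peaks (x axis), for autosomes and for X where at least 10 windows fall in a group; bars are 95% exact binomial intervals. On autosomes the ratio drops from 1.70 in windows without a shared peak to 1.03 in the windows with most.

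The windows with most peaks were on chromosomes 10 and 19. Chromosome 10 from 80000001 to 81000000 held 109 ES peaks and 103 MEF peaks, of which 40 and 42 were shared. The adjoining window, from 79000001 to 80000000, held 85 ES and 103 MEF peaks. Chromosome 19 from 5000001 to 6000000 held 82 ES and 102 MEF peaks, and 47 of the ES peaks were shared. The 3 windows with the largest difference in the percentage of peaks not shared held fewer ES than MEF peaks. The rule favours windows with unequal peak numbers, because the shared peaks of both lists were nearly equal in number there. The MEF shares given below therefore partly restate the rule. On chromosome 4 from 13000001 to 14000000, 1 of 4 ES peaks and 17 of 20 MEF peaks had no partner. On chromosome 1 from 44000001 to 45000000 the numbers were 2 of 8 ES peaks and 23 of 29 MEF peaks. On chromosome 6 from 17000001 to 18000000 they were 3 of 14 ES peaks and 20 of 29 MEF peaks. MEF peaks made up 83.3% of the peaks in the chromosome 4 window (95% Wilson interval 64.1 to 93.3), 78.4% in the chromosome 1 window (62.8 to 88.6) and 67.4% in the chromosome 6 window (52.5 to 79.5), against 54.7% in the whole data set. The interval of the chromosome 6 window includes the genome-wide value, and these windows were the extremes among all windows.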

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

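Peaks outside the numbered chromosomes and X enter no comparison between chromosomes. Groups of such sequences with more than 3 peaks in a list were flagged. This limit does not tell whether the peaks are CTCF sites. The mitochondrial genome carried 15 ES peaks and 21 MEF peaks, of which 13 and 20 were shared. Together they covered 35.6% (ES) and 48.4% (MEF) of the 16326 bp up to the last mitochondrial peak. Their median score was 345 in ES cells and 200 in MEFs, at or above the score of 99.6% and 99.1% of all peaks of the same list. Random and unplaced sequences carried 82 ES peaks and 101 MEF peaks, with 26 shared in either list. Chromosome Y carried 2 ES peaks and 1 MEF peak and was not flagged.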

How the results depend on the processing

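Of 41 alternative values, 19 stayed within the counting interval (for the chance overlap, the range of placements; for peak numbers, 1.5 times) and 22 moved beyond it; with intervals this narrow, small shifts count as moved. The percentage of ES peaks shared (26.1%) was 22.8% with an overlap of 50% of both peaks, 27.3% with midpoints within 500 bp, 30.6% in the higher-scoring 50% of the list and 23.2% with the MEF list cut to the ES length. The percentage of MEF peaks shared (21.6%) was 18.9%, 22.6%, 28.6% and 23.0% in the same order. Among alternatives chosen after seeing the data, midpoints within 1000 bp gave 31.4% (ES) and 26.1% (MEF), and the higher-scoring 50% of both lists set against each other gave 22.1% and 18.3%. Moving the other list by 10 kb, also chosen after seeing the data, raised the chance overlap to 3.18% (ES) and 2.63% (MEF). With an overlap of 50% of both peaks, the highest-scoring 10% of peaks were shared at 46.2% (ES) and 51.7% (MEF), and peaks on X at 14.5% (ES) and 8.40% (MEF). On X, cutting the MEF list gave 14.3% for ES peaks, and the higher-scoring 50% of the MEF list gave 13.8%. The MEF to ES ratio on X fell to 1.41 with the MEF list cut, while its excess over the autosomal ratio was 1.42 there, 1.33 in the higher-scoring 50% of both lists and 1.45 in the full lists. In windows of 500 kb, 23.5% of ES-only peaks lay in the 10% of windows with most shared peaks. The fits of annotation, motif content and gene lists were not run. No paired analysis was possible because each cell type has 1 library. Read depth is unknown, so its effect on the list lengths was not tested.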

Other observations

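The tests of explanations in this part, the windows named here and the comparison of close pairs were chosen after seeing the data. Windows were ranked by the number of ES-only peaks less that of MEF-only peaks, or the reverse. By this measure, ES-only peaks were most in excess on chromosome 18 from 37000001 to 38000000. This window held 53 ES and 23 MEF peaks, of which 47 and 17 had no partner. MEF peaks made up 30.3% of the peaks there (95% Wilson interval 21.1 to 41.3), against 54.7% genome-wide. Chromosome 11 from 107000001 to 108000000 followed with 56 ES and 31 MEF peaks, of which 44 and 19 had no partner. Chromosome 17 from 27000001 to 28000000 was equal to it by this measure, with 73 and 46 peaks, of which 57 and 32 had no partner. MEF peaks were most in excess on chromosome 7 from 26000001 to 27000000 (19 ES and 48 MEF peaks), on chromosome 2 from 117000001 to 118000000 (26 and 55) and on chromosome 1 from 93000001 to 94000000 (24 and 48). These windows are the extremes of all windows by the ranking measure, so their intervals overstate how far they stand apart.

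Peaks that came in close pairs were shared more often. Of ES peaks with another ES peak within 1 kb, 46.9% overlapped a MEF peak (95% interval 45.6 to 48.3), against 23.3% (22.9 to 23.7) of the others. For MEF peaks the values were 42.0% (40.8 to 43.2) and 19.01% (18.7 to 19.4). After the other list was moved by 10 kb, the overlap was 5.28% and 2.90% for ES peaks and 4.22% and 2.43% for MEF peaks; a move of that size does not keep the density of peaks within 1 kb, so the part that close spacing itself plays was not tested.

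Few peaks were common to both lists, and the tables argue against 1 simple technical explanation. If small offsets between called positions kept matching sites from overlapping, a wider tolerance would raise the overlap well beyond chance, but the excess over a 10 kb move was 22.9% of ES peaks for overlapping peaks and 23.9% within 1000 bp. Weak peaks let in by the peak caller's threshold remain open: the highest-scoring 10% of the ES list were shared at 49.9%, and the score is not defined, so these peaks need not hold the strongest sites. A difference in binding between the cell types, or in their genetic background or library, was not tested and stays open too, as 1 library per cell type confounds them.

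Part of the high MEF to ES ratio on X may belong to the wider trend in which MEF peaks are in excess where shared peaks are sparse. The X ratio was 1.15 times that of autosomal windows with as many shared peaks (counting interval 1.05 to 1.25, single autosomes 0.854 to 1.09) and 1.17 times that of windows with as many peaks of both lists together (1.07 to 1.27, single autosomes 0.869 to 1.09), so neither interval clears the autosomes. In the 66 X windows with fewer than 10 peaks of both lists together the ratio was 2.47 (1.96 to 3.12, widened by the spread between autosomes). In the 190 autosomal windows of this kind it was lower, 1.504 (1.34 to 1.69). Single autosomes ran there from 0.957 on chromosome 7 to 3.25 on chromosome 8 (12 ES and 39 MEF peaks, interval 1.67 to 6.82), a range that includes X. They differed from each other only 1.10 times as much as counting error gives (variance ratio). The lower bound of X lay below the ratios of chromosomes 5 (2.05), 8 and 10 (2.22), so X did not clear the single autosomes here either. Density was also not matched within this class, as 20 of the X windows and 32 of the autosomal windows held fewer than 5 peaks. Whether a lower density of peaks of any kind accounts for the X ratio in sparse windows therefore stays undecided. In the windows with 10 or more peaks, X was 1.08 times the matched autosomal ratio (0.984 to 1.19), within the 0.865 to 1.09 of single autosomes, and there the density trend and a separate effect of X cannot be told apart, because the interval spans both; no biological explanation was tested, since the sex of the cells was not used here.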
